A study of Rattus norvegicus with 21 samples.

How the data were processed

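RNA of rat spinal cord was measured on 21 2-colour arrays, in 7 groups of 3 replicates. Each array carried the RNA of a sample beside a pool of culture RNA as reference. Freshly dissected cord (the Uninjured group), unpooled PBS-treated 4 hr cultures (Injured 4 hr) and the CKIN, MP and acetaminophen (Acet) cultures were compared with a pool of PBS-treated 4 hr cultures. Indomethacin (Indo) cultures were compared with a pool of ethanol-treated (ETOH) cultures, and NS398 cultures with a pool of DMSO-treated cultures.

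The values deposited by the authors are log2 ratios of sample over reference pool. The log base was read from the values, since exact logarithms of ratios of small whole numbers recur among the values of the treatment arrays. The order of the RNAs in the sample titles was taken as numerator and denominator, which is likely but not stated. Lists fixed in advance as a check were to be higher if that order holds. Those were early response, cytokine and heat shock genes in the injury comparison and glucocorticoid genes in MP. The early response and cytokine lists were shifted up, while the heat shock and glucocorticoid lists did not shift as a whole. Dyes, scanner, background correction, normalization and spot filter are not given in the sources used here. The column medians lay far apart, so the deposited values were taken as not normalized between arrays. Blank cells were treated as missing spots. The table held 5376 probes, of which 4962 had a value on at least 1 array. Between 3092 and 4916 probes were measured per array, and the number of arrays limits the precision. Gapdh was spotted 51 times and its spots were averaged. Different probes of other genes were kept apart. Gene symbols came from the deposited annotation and were updated by gene identifier where the rat reference table held it, for 4375 of 4423 probes with 1 symbol. A further 545 measured probes had no gene listed. They were counted but not named. No genome build or coordinates were used here.

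Each array was centred on the median of its measured probes, and changes are relative to that median. All 21 arrays entered 1 linear model with 1 coefficient per group in limma 3.58.1 under R 4.3.3, with moderated statistics and Benjamini-Hochberg adjustment within each comparison. A probe was tested where at least 2 of 3 arrays of each compared group had a value. The threshold was a 2-sided adjusted p of 0.05. There were 11 comparisons. CKIN, MP and Acet were set against the Injured 4 hr arrays, so that the PBS pool cancels if it is the same. The titles of the treatment arrays name the vehicle without the word pooled. That these references were pools, and for PBS the same pool, was taken as likely. Indo and NS398 were tested against 0, since no unpooled ethanol or DMSO culture is among these samples. The pool is then a single control sample whose own spread is outside the test. The Injured 4 hr arrays tested against 0 compare like RNA with like RNA and give a rough background of such a test. The p-values measure only the spread between these samples, since nothing in the labels says whether replicates were separate animals or cultures.

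The groups, comparisons, tests, filters, 26 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names, per comparison, the 10 probes with the largest rise and the 10 with the largest fall among those that passed with the same sign in every measured array, up to 4 passing members of each list, and 15 panel genes in any case. The text takes up to about 30 of them per main comparison, and fewer where few passed. Each gene described below as having risen or fallen had that sign in every measured array of the treated group. Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, with the estimated correlation and with fry beside it. For these tests each gene entered through its probe with most values, if it had a value in every group. Missing values were filled with the group mean. Filled values add no spread, so the spread of genes with missing spots is understated there, most in groups with many missing spots. Lists with fewer than 5 measured genes were not tested. List counts come from the fit of the list tests, not from the probe fits, and can differ from the probe calls. They are adjusted over all genes of that fit. Where they differ in centred ratios or against the other treatments, counts adjusted over the list alone are given as well. Counts in corrected ratios are over all genes of that fit.

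A further setting was chosen after seeing the data. Ratios varied with the mean ratio of the Injured 4 hr arrays and with the source plate of the probe. Intensities are not given, so that mean ratio stood in for brightness, an assumption that could not be checked. A loess curve (span 0.4) of each array on that stand-in was subtracted, and the residuals were centred on each source plate with at least 20 probes. These values are called corrected. The correction sets the Injured 4 hr arrays near 0 by construction, so it can say nothing on them alone, and errors of the stand-in enter the corrected differences of the other groups from them. The text leads with genes that passed with the same sign in both the centred and the corrected values. Also chosen after seeing the data were a block for array set, which parts arrays with more than 1100 missing spots from the others, and a comparison of each treatment with the mean of the other 4 treatments.

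The procedure was tested on simulated data built on the real spread, with 200 changed probes. With centred ratios and no added trend, 17% of log2 changes of 1 and 87% of log2 changes of 2 were recovered in the injury comparison, with 3 false calls. The same figures were 9% and 73% with 4 false calls for MP, and 51% and 98% with 9 false calls for NS398. A linear trend on the mean ratio of the Injured 4 hr arrays, the same stand-in that the correction uses, was then added. False calls rose to 335 for NS398 in centred ratios and were 18 in corrected ones. For injury they were 45 and 25. Neither brightness itself nor a plate effect was simulated, so these counts cannot say whether the correction removes a real bias with brightness.

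Alternatives were deposited ratios without centring, quantile and scale normalization, probes measured on all 21 arrays, no filter on missing values, removal of the probes with the smallest spread, array weights, a fit on the compared arrays only, robust moderation, the PBS pool as control, a replicate block, and omission of each array in turn. Shared calls of treatments were set beside the number expected of independent lists. The correlation among CKIN, MP and Acet, and the effect of each treatment on injury-changed genes, were set beside 100 simulations of unchanged groups with the same shared controls. For the injury-changed genes these draw the injury change from its shrunken estimate and repeat the injury test on each draw, a form set after the data had been seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.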

Results

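The series, titled as a study of anti-inflammatory compounds in spinal cord injury, holds expression ratios of rat spinal cord on 21 arrays. There were 3 arrays in each of 7 groups: freshly dissected cord (Uninjured), cultures kept for 4 hr with PBS vehicle (Injured 4 hr), and cultures treated with CKIN, MP, acetaminophen, indomethacin or NS398. The labels give only letters for CKIN and MP. From knowledge of the field, not from the labels, they are read as cytokine inhibitors and methylprednisolone, a synthetic glucocorticoid. Acetaminophen is an analgesic, indomethacin inhibits both cyclooxygenases, and NS398 prefers cyclooxygenase 2. Between 3092 and 4916 probes were measured per array. All 3 CKIN arrays, all 3 Indo arrays, 2 MP arrays, 1 Acet array and 1 NS398 array had more than 1100 missing spots. These 10 sparse arrays are treated as an array set.

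The deposited ratios were not centred. Array medians ran from -4.12 to -3.09 in Uninjured, from -2.26 to -2.12 in Injured 4 hr and from -1.62 to 0.70 in the treatments. Exact logarithms of ratios of small whole numbers made up between 8.08% and 13.2% of the values on each of the 15 treatment arrays and between 0.320% and 1.19% on each of the 6 Uninjured and Injured 4 hr arrays. This mark of scanning or processing parts the same arrays as the comparisons of CKIN, MP and Acet with Injured 4 hr. Spot intensities are not given. In the Injured 4 hr group, where both channels carried PBS culture RNA, the spots of the abundant transcript Gapdh averaged -0.04 ± 0.07 (SD, n = 3), far above the array medians. Group means of Gapdh were 0.16 in Uninjured and lay between 0.48 and 1.28 in the treatments.

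**Figure D1:**
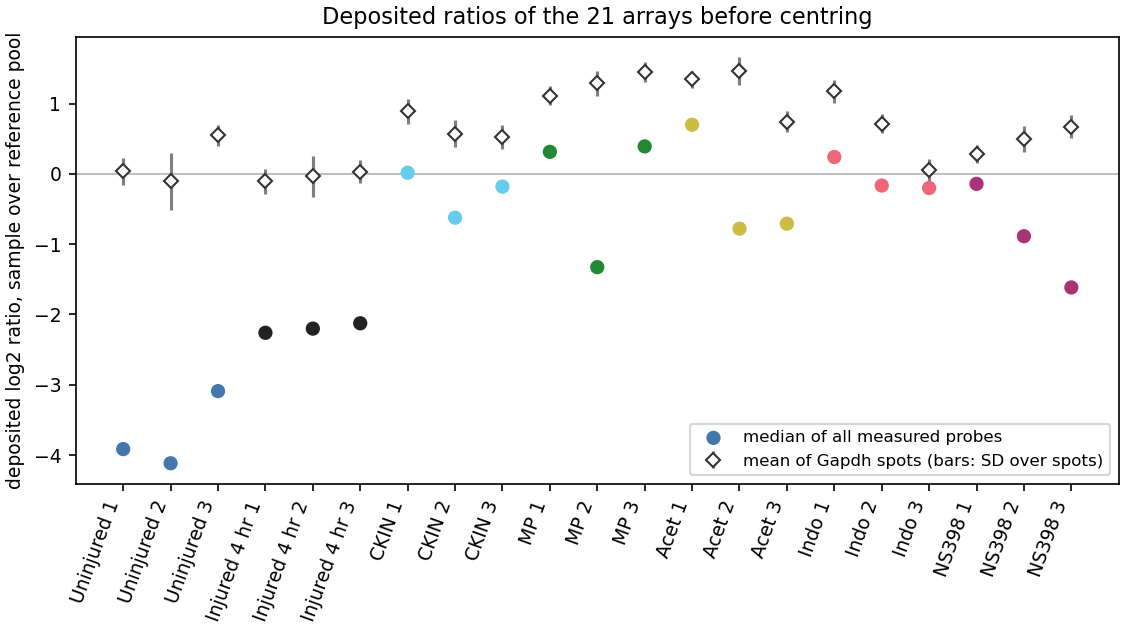
Deposited log2 ratio of sample over reference pool (vertical axis) for the 21 arrays (horizontal axis). Filled circles give the median of all measured probes and diamonds the mean of the Gapdh spots with their SD; medians of the Uninjured arrays lie between -4.12 and -3.09, while Gapdh stays near or above 0 on every array.

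The comparison of Injured 4 hr with Uninjured asks what changes when cord is cut and cultured for 4 hr. Several chemokine, inducible chaperone and early response genes rose, while most measured neuronal and astrocyte markers fell relative to the array median. Ccl4, which attracts monocytes, rose by a log2 change of 3.75 ± 0.64 (SE, n = 3 per group; limma adjusted p = 0.000535). Cxcl2, which attracts neutrophils, rose by 3.73 ± 0.56 (adjusted p = 0.000164), and the inducible chaperone Hspa1a by 3.60 ± 0.46 (adjusted p = 6.53e-05). Among the falls, the astrocyte water channel Aqp4 changed by -3.55 ± 0.78 (adjusted p = 0.0046), and Vamp1, a protein of synaptic vesicles, by -3.35 ± 0.43 (adjusted p = 6.52e-05).

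Of 24 measured cytokines and chemokines, 5 rose and 1 fell, and the list as a whole shifted up (camera adjusted p = 5.17e-05; adjusted p = 0.175 with an estimated correlation, and 0.00355 in corrected ratios, where 8 rose and 1 fell). Besides Ccl4 and Cxcl2, the neutrophil attractant Cxcl1 rose by 2.86 ± 0.53, the interferon-induced Cxcl10 by 1.82 ± 0.32, and the cytokine Il1a by 1.18 ± 0.33. Early response genes shifted up with 4 of 16 past the threshold (6 adjusted over the list alone; camera adjusted p = 5.17e-05; adjusted p = 0.0987 with an estimated correlation, 0.00355 in corrected ratios). They included the stress transcription factor Atf3 at 2.17 ± 0.38 and the phosphatase Dusp1 at 1.60 ± 0.36. Of 17 NF-kB components and targets, 4 rose (camera adjusted p = 0.0066; adjusted p = 0.366 with an estimated correlation, 0.0207 in corrected ratios). Examples are Ptgs2, which encodes cyclooxygenase 2, at 2.38 ± 0.38, the inhibitor Nfkbia at 1.88 ± 0.47 and the signalling brake Socs3 at 1.27 ± 0.35. Ptgs2 was the member of the 17-gene prostanoid list that rose. That list shifted up in centred ratios (camera adjusted p = 0.000758; adjusted p = 0.0334 with an estimated correlation) and not in corrected ones (adjusted p = 0.172). With 1 array left out, the call of Il1a ended without Injured 4 hr replicates 1 and 3 (at 1.03 and 1.23) and Uninjured replicate 1 (1.04), that of Socs3 without Injured 4 hr replicates 1 and 2 (1.24 and 1.16) and Uninjured replicate 3 (1.02), and that of Nfkbia without Uninjured replicate 3 (1.61).

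Of 19 heat shock genes and chaperones, 3 rose and 8 fell (3 and 11 adjusted over the list alone), and the list did not shift as a whole (camera adjusted p = 0.0924). The 3 that rose were inducible: Hspa1a, with a second probe at 2.44 ± 0.49, Hspa1b at 3.3 ± 0.45, and the haem-degrading enzyme Hmox1 at 2.06 ± 0.65 (n = 3 and 2). Zfp36, which destabilises cytokine mRNAs, rose by 2.39 ± 0.54, and the transcription factor Cebpb by 1.62 ± 0.44. The call of Hmox1 ended without each Injured 4 hr replicate in turn (at 2.06, 1.87 and 2.25) and without Uninjured replicate 2 (2.06), and that of Cebpb without Injured 4 hr replicates 1 and 3 (1.46 and 1.61) and Uninjured replicate 3 (1.38). Several panel genes did not pass: Il1b at 0.75 ± 0.38 and -0.05 ± 0.47 on 2 probes, Il6 at 1.25 ± 0.49, Tnf at 1.18 ± 0.54, and Ccl2 at 0.85 ± 0.49 and 1.07 ± 0.40. In corrected ratios Ccl2 passed on both probes, at 1.63 and 1.48, and Il6 at 1.77.

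Of 33 neuronal markers, 21 fell and none rose in centred ratios (22 fell adjusted over the list alone; camera adjusted p = 3.59e-07; adjusted p = 0.216 with an estimated correlation). In corrected ratios 11 fell and 3 rose, with a list median of -0.60 (adjusted p = 0.0207 with an estimated correlation). Genes of synaptic vesicle release stood among them: Snap25 changed by -3.19 ± 0.50, and Thy1, a neuronal surface protein, by -3.10 ± 0.44 (n = 3 and 2). Stmn2, which acts in neurite growth, changed by -2.81 ± 0.36, Nsf, needed for vesicle fusion, by -3.08 ± 0.50, and the synuclein Sncb by -2.89 ± 0.39. Of 14 astrocyte markers, 10 fell (11 adjusted over the list alone; camera adjusted p = 3.85e-05; adjusted p = 0.171 with an estimated correlation). In corrected ratios 6 of 13 fell, with a median of -0.76 (adjusted p = 0.008 with an estimated correlation). Besides Aqp4, the bicarbonate transporter Slc4a4 changed by -2.39 ± 0.36, the growth factor receptor Fgfr3 by -2.28 ± 0.33, and Gfap by -2.11 ± 0.53 (corrected -1.10, but 0.16 under scale normalization). The Gfap call ended without Injured 4 hr replicate 2 (-1.97) and without Uninjured replicate 2 (-1.94). The angiogenic factor Vegfa changed by -2.89 ± 0.39, the neurotrophin receptor Ntrk2 by -2.42 ± 0.46 (n = 3 and 2), the matrix proteoglycan Bcan by -1.94 ± 0.36 and -1.93 ± 0.41 on 2 probes, the GABA receptor subunit Gabrg1 by -2.13 ± 0.42, and the antioxidant enzymes Prdx5 and Sod3 by -2.51 ± 0.42 (n = 3 and 2) and -2.17 ± 0.34. The myelin gene Mbp did not pass, at -1.42 ± 0.57, and turned to 0.10 in deposited ratios.

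Microglia and macrophage markers counted 1 rise among 12 in centred ratios (0 adjusted over the list alone; camera adjusted p = 0.156) and 5 rises with a list median of 0.77 in corrected ones (adjusted p = 0.008 with an estimated correlation). Oxidative phosphorylation (12 of 20 fell), proteasome and ubiquitin (18 of 26), cholesterol synthesis (6 of 11), glycolysis and hypoxia (11 of 21 fell, 1 rose) and antioxidant defence (12 of 25 fell, 2 rose) shifted down in centred ratios. Adjusted over each list alone, 17, 20, 8, 12 and 14 of them fell, and 1 and 3 rose in the last 2 lists. Myelin genes shifted down (4 of 13 fell; camera adjusted p = 0.0493) and blood and granulocyte genes up (0 of 9 passed; camera adjusted p = 0.0493), with estimated-correlation adjusted p of 0.529 and 0.311. None of the 5 lists before these passed with an estimated correlation, where adjusted p ran from 0.103 to 0.388, and none passed in corrected ratios, where 1 of 20, 1 of 26, 0 of 10, 5 of 21 and 3 of 24 genes fell.

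In limma, 690 of 4823 probes passed in centred ratios, 39 higher and 651 lower. In corrected ratios 295 passed, 106 higher and 189 lower, and 191 passed in both with the same sign, 27 higher and 164 lower; 6 of the 683 called probes with a corrected value had the opposite sign there. The split between higher and lower rests on the scaling. Deposited ratios, whose median shifts by 1.47 between the groups, gave 2428 probes, 99.4% of them higher; quantile normalization gave 20 (70% higher) and scale normalization 33 (87.9% higher), against 5.65% in centred ratios. The 33 named probes kept their direction under each scaling, except Gfap under scale normalization; 21 kept their call in deposited ratios, 12 under quantile and 15 under scale normalization, and 33 in corrected ratios. Leaving out 1 array gave 388, 357 and 385 probes without Injured 4 hr replicates 1, 2 and 3, and 354 and 424 without Uninjured replicates 2 and 3.

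**Figure D2:**
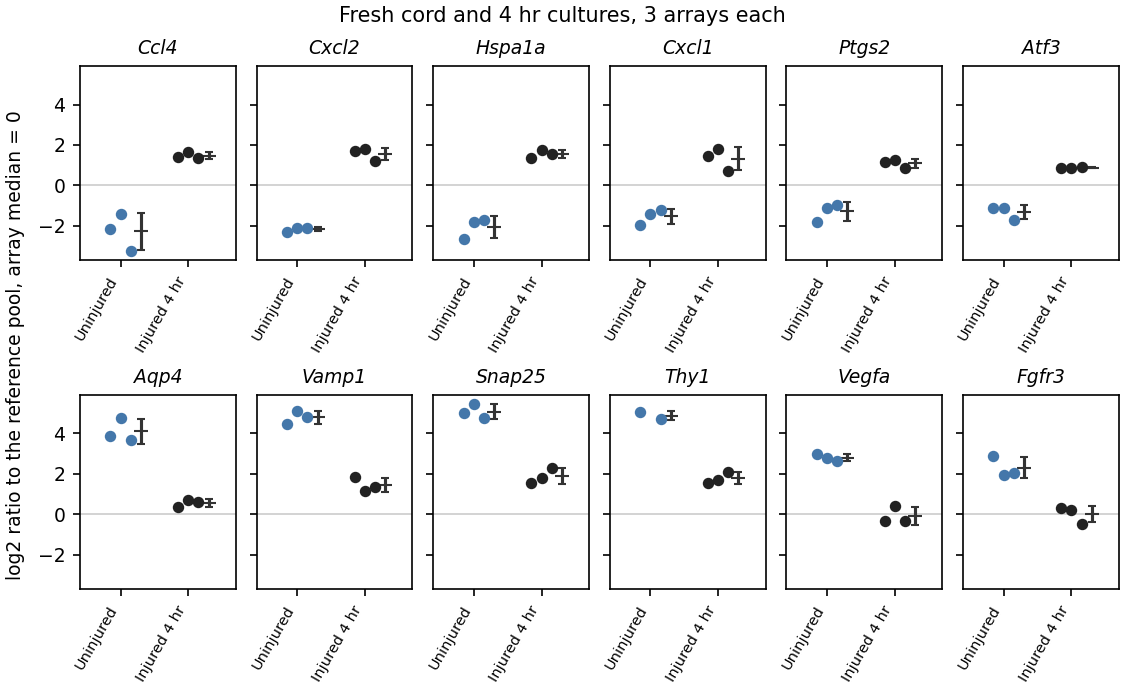
Log2 ratio to the PBS culture pool with each array's median at 0 (vertical axis) for 12 genes in the Uninjured and Injured 4 hr groups. Points are arrays and bars the mean with SD; Ccl4 and Cxcl2 are higher in all 3 cultures (changes of 3.75 and 3.73), and Aqp4 and Vamp1 are lower in all 3 (changes of -3.55 and -3.35).

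The CKIN comparison asks how cytokine inhibition changes the cultured cord. Relative to the Injured 4 hr arrays, Barhl1, a transcription factor of neural development, rose by 3.43 ± 0.65 (n = 3 per group; limma adjusted p = 0.00315). Ptges, the enzyme that makes prostaglandin E2, fell by 2.02 ± 0.47 (adjusted p = 0.0081), and the membrane glycoprotein Gpm6b by 2.74 ± 0.51 (adjusted p = 0.00315). The histamine receptor Hrh1 changed by -2.72 ± 0.54 (n = 2 and 3) and the ribosomal pseudogene Rps4x-ps9 by -2.97 ± 0.45. These 5 passed in both centred and corrected ratios.

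Other genes passed in centred ratios only. Cxcl1 changed by -2.26 ± 0.59 (n = 2 and 3; corrected -1.38, adjusted p = 0.213), Hmox1 by -2.53 ± 0.57 (corrected -0.62), and Nfkbia by -1.73 ± 0.47, which turned to 0.19 in deposited ratios. Cebpb changed by -2.75 ± 0.49 (n = 2 and 3), Hspa1a by -2.26 ± 0.46 and -1.95 ± 0.48 on 2 probes, Col1a2, a fibrillar collagen, by -2.29 ± 0.48, and the potassium channel Kcnj3 by 1.62 ± 0.39 (n = 2 and 3). Il1b passed on 1 probe, at -2.17 ± 0.47, and not on the other, at -0.42 ± 0.43 (n = 2 and 3). The myelin genes Ugt8 and Mobp changed by -2.67 ± 0.49 and -2.53 ± 0.59, and Mbp by -2.25 ± 0.57. S100b, an astrocyte protein, changed by -2.29 ± 0.53 on 1 probe. On the other it changed by -1.98 ± 0.54, which turned to 0.17 against the PBS pool and 0.11 in corrected ratios. With 1 array left out, that S100b call ended without CKIN replicate 3 (-1.61) and each Injured 4 hr replicate (-1.92, -2.01 and -2.01), that of Nfkbia without each Injured 4 hr replicate (-1.75, -1.74 and -1.71), that of Cxcl1 without Injured 4 hr replicate 2 (-2.02), that of the second Hspa1a probe without Injured 4 hr replicate 1 (-1.67) and that of Mbp without CKIN replicate 3 (-1.85). Ribosomal proteins fell most broadly, 53 of 66 in centred ratios (62 adjusted over the list alone; camera adjusted p = 9.38e-11), but with an estimated correlation adjusted p = 0.788, and in corrected ratios 1 of 65 fell. Examples are Rpl23 at -2.13 ± 0.47, Rpl31 at -2.12 ± 0.49, and Rps24 at -2.32 ± 0.49, which turned to 0.24 against the PBS pool. Heat shock (11 of 19 fell; 14 adjusted over the list alone), oxidative phosphorylation (11 of 20; 15), proteasome (9 of 26) and myelin lists (7 of 13; 9) also shifted down in centred ratios, each with adjusted p = 0.788 with an estimated correlation and with none called in corrected ratios. Of 24 cytokines and chemokines 7 fell, and the list did not shift as a whole (camera adjusted p = 0.322).

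In limma, 749 of 3737 probes passed, 55 higher and 694 lower. Corrected ratios gave 28 (9 higher, 19 lower), of which 24 were shared with the same sign. Of the 745 called probes with a corrected value, 122 had the opposite sign there. The difference in small whole-number ratios between treatment and Injured 4 hr arrays coincides with this comparison and cannot be removed. All CKIN arrays are sparse and all Injured 4 hr arrays are not: with array set as a block 8 probes passed and 0 of the 22 named probes kept their call. Deposited ratios, shifted by 1.54, gave 2232 probes, 99.96% of them higher, and quantile normalization 618 (25.2% higher), against 7.34% in centred ratios. Without CKIN replicate 3, 323 probes passed, and without Injured 4 hr replicates 1, 2 and 3 there were 272, 237 and 205.

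The MP comparison asks how methylprednisolone changes the cultured cord. Barhl1 rose by 4.23 ± 0.65 (n = 3 per group; limma adjusted p = 0.00546), and Ptges fell by 2.28 ± 0.47 (adjusted p = 0.0178). Nos1ap, an adaptor of neuronal nitric oxide synthase, changed by -2.39 ± 0.43 (adjusted p = 0.00889), and Rps4x-ps9 by -2.74 ± 0.45. The neurotrophin Ntf3 changed by -2.39 ± 0.39 on 1 probe, while its other probe, at -0.97 ± 0.40, did not pass. The enzyme Ugt2b37 changed by -2.31 ± 0.44. Il1a fell by 1.30 ± 0.34 (adjusted p = 0.0449), though it stood at 0.69 in deposited ratios, whose median is shifted by 1.66, and at -1.22 (adjusted p = 0.065) in corrected ones. With 1 compared array left out, the call of Rps4x-ps9 ended without Injured 4 hr replicate 3 (-2.60), that of Nos1ap without MP replicates 1 and 3 (-2.24 and -2.19) and Injured 4 hr replicates 2 and 3 (-2.40 for both), and those of Ptges (between -2.39 and -2.07) and Ugt2b37 (between -2.33 and -2.24) without MP replicate 3 and each Injured 4 hr replicate. The call of Il1a ended in all omissions but that of MP replicate 2 (between -1.39 and -1.15).

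Of 28 glutamate and GABA receptor genes 2 fell (3 adjusted over the list alone), of 28 voltage-gated channels 3 fell and 1 rose (5 and 2 adjusted over the list alone), and of 22 apoptosis genes 3 fell (4 adjusted over the list alone). None of these lists shifted as a whole (camera adjusted p = 0.889, 0.494 and 0.494). Examples, each with a positive value in deposited ratios and each no longer called when any 1 compared array other than MP replicate 2 was left out, were the glutamate receptors Grm6 at -1.94 ± 0.39 (deposited 0.041) and Grik1 at -1.76 ± 0.42 (0.22), the calcium channel subunits Cacnb2 at -1.90 ± 0.50 (0.085) and Cacna1e at -1.73 ± 0.44 (0.26), and the apoptosome component Apaf1 at -1.80 ± 0.46 (0.19). The probes of Nos3, the endothelial nitric oxide synthase, disagreed: 1 rose by 1.47 ± 0.35, another changed by -1.78 ± 0.39 (0.20 in deposited ratios), and the other, at -0.84 ± 0.38 (n = 2 and 3), did not pass. Both Nos3 calls also ended in all omissions but that of MP replicate 2. Of 20 glucocorticoid responsive genes none passed (camera adjusted p = 0.813). This list had been fixed in advance as a check, to be higher in MP if the order of the titles holds, and the check was not met. Simulated data recovered 9% of log2 changes of 1 in this comparison, so small rises of single genes would mostly be missed. Of 24 cytokines and chemokines Il1a was the 1 that passed, and Ptgs2 at -0.40 ± 0.39, Ccl2 at -0.64 ± 0.49 and -0.69 ± 0.40, and Nfkbia at -0.74 ± 0.47 did not. Ribosomal proteins shifted down in centred ratios with 1 of 66 past the threshold (0 adjusted over the list alone; camera adjusted p = 1.02e-07; adjusted p = 0.928 with an estimated correlation). In corrected ratios neuronal markers shifted up with 2 of 33 past the threshold (camera adjusted p = 5.25e-05; adjusted p = 0.0677 with an estimated correlation), and astrocyte markers shifted down with 0 of 13 (camera adjusted p = 0.0154; adjusted p = 0.118 with an estimated correlation).

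In limma, 90 of 4392 probes passed, 2 higher and 88 lower, in a comparison that coincides with the difference in small whole-number ratios as well. Corrected ratios gave 17 (4 higher, 13 lower), with 15 shared. Deposited ratios gave 3171, all higher, and quantile normalization 35 (25.7% higher). Single arrays decided the count: 9, 598 and 4 probes passed without MP replicates 1, 2 and 3, and 9, 5 and 3 without Injured 4 hr replicates 1, 2 and 3, when between 2 and 5 of the 14 named probes kept their call in all cases but the omission of MP replicate 2, where all 14 did.

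The acetaminophen comparison asks how a weak cyclooxygenase inhibitor changes the cultured cord. Barhl1 rose by 3.18 ± 0.66 (n = 3 per group; limma adjusted p = 0.0239). Ptges fell by 2.61 ± 0.48 (adjusted p = 0.0167), and the insulin-like growth factor binding proteins Igfbp2 and Igfbp6 by 2.55 ± 0.54 and 2.28 ± 0.34 (adjusted p = 0.0262 and 0.00484). Connective tissue and matrix genes fell with them, namely Col1a2 by 2.44 ± 0.48, the matrix protein Mgp by 2.23 ± 0.51 (corrected -1.64, adjusted p = 0.116) and the protease inhibitor Timp1 by 2.18 ± 0.46 (corrected -1.68, adjusted p = 0.0842). None of these calls held in all 6 omissions of 1 compared array: that of Igfbp6 ended without Injured 4 hr replicates 2 and 3 (-2.16 and -2.09), those of Barhl1 (between 3.00 and 3.36) and Ptges (between -2.72 and -2.40) without Acet replicate 1 and each Injured 4 hr replicate, and those of Igfbp2, Col1a2, Mgp and Timp1 in all but the omission of Acet replicate 2.

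Of 20 vascular and connective tissue genes 2 fell (3 adjusted over the list alone), and of 19 genes of matrix remodelling 4 fell, and neither list shifted as a whole (camera adjusted p = 0.769 and 0.949). Nos1ap changed by -2.31 ± 0.43 and Apaf1 by -2.17 ± 0.46. Bid, which promotes cell death, changed by -1.69 ± 0.34 and Grm6 by -1.86 ± 0.39, with deposited values of 0.24 and 0.070. Dhh, a hedgehog signal of Schwann cells, changed by -2.21 ± 0.44, and the calcium channel subunit Cacnb1 rose by 1.61 ± 0.37. Col1a1 fell by 1.56 ± 0.33 on 1 probe, which stood at 0.37 in deposited ratios, and did not pass on the other, at -0.49 ± 0.45. Ptgs2, at -1.42 ± 0.39, and Ccl2, at -1.52 ± 0.49 and -0.94 ± 0.40, did not pass. Ribosomal proteins shifted down in centred ratios with 0 of 66 past the threshold (camera adjusted p = 3.31e-05; adjusted p = 0.982 with an estimated correlation).

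In limma, 62 of 4735 probes passed, 5 higher and 57 lower, against 31 in corrected ratios (9 higher, 22 lower) and 24 in both. This comparison, too, coincides with the difference in small whole-number ratios. Deposited ratios, shifted by 1.64, gave 3372, all higher, and quantile normalization 47 (34% higher, against 8.06% in centred ratios). The calls rest on single arrays: 2, 122 and 11 probes passed without Acet replicates 1, 2 and 3, and 1, 0 and 0 without Injured 4 hr replicates 1, 2 and 3, where 1, 0 and 0 of the 14 named probes kept their call.

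Some changes were common to the treatments. In corrected ratios 4 probes passed with the same sign in all 5 treatments: Ptges, at -1.99 in CKIN, -2.11 in MP, -2.50 in Acet, -1.80 in Indo and -1.23 in NS398, Rps4x-ps9 between -2.03 and -1.40, Barhl1 between 2.84 and 4.30, and the cytokine gene Il3 between 1.28 and 1.74. In all, 10 probes passed in at least 4 treatments, among them Nos1ap, the adrenergic receptor Adrb1 and Ugt2b37.

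**Figure D3:**
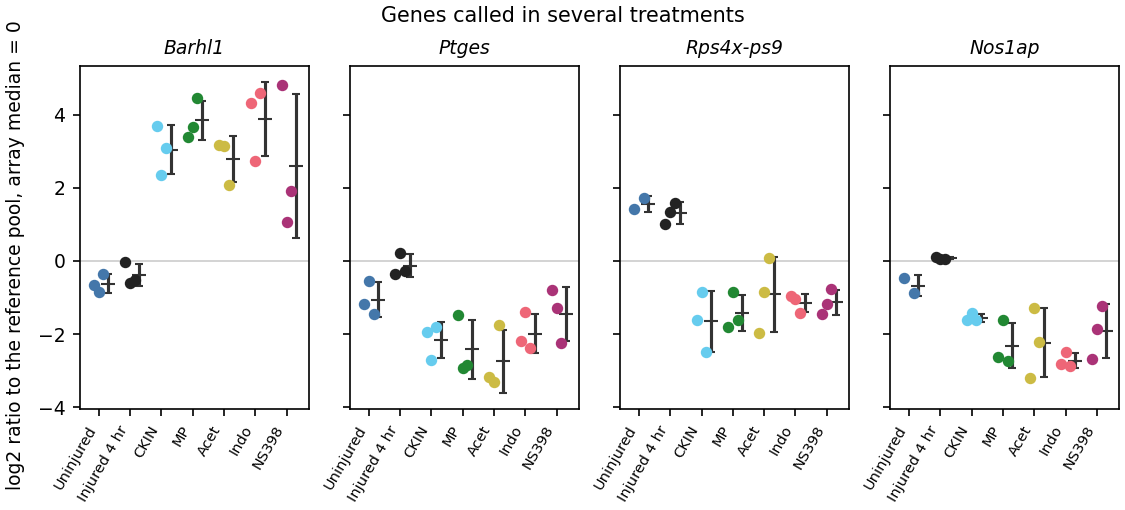
Log2 ratio to the reference pool with each array's median at 0 (vertical axis) for 4 genes in the 7 groups. Points are arrays and bars the mean with SD; Barhl1 is higher, and Ptges and Nos1ap lower, in the 15 treatment arrays than in the 3 Injured 4 hr arrays.

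The indomethacin comparison asks how inhibition of both cyclooxygenases changes the cultured cord, with the pooled ethanol cultures as the only control. Barhl1 rose by 3.88 ± 0.46 (n = 3; limma adjusted p = 1.14e-05) and the glutamine transporter Slc38a1 by 2.40 ± 0.33 (adjusted p = 3.95e-05). Probes of 4 cytoskeleton and transport genes rose as well, Map1a by 1.99 ± 0.32, Kif1b by 2.09 ± 0.24, Map1b by 2.07 ± 0.28 and Nefl by 1.71 ± 0.40, while second probes of Kif1b, Map1b and Nefl, at 0.27 ± 0.33 (n = 2), -0.13 ± 0.31 and -0.02 ± 0.37, did not pass. Several receptor genes fell, the muscarinic receptor Chrm5 by 2.97 ± 0.55, the glycine receptor Glra2 by 2.34 ± 0.36 (n = 2) and the kainate receptor Grik1 by 2.32 ± 0.30. Chrm5 stood at -1.97 without Indo replicate 1.

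Of 28 glutamate and GABA receptor genes 7 fell (9 adjusted over the list alone), Gria2 by 1.09 ± 0.29 among them (-0.66 and no longer called without Indo replicate 2), and of 28 voltage-gated channels 3 fell and 1 rose, with Cacnb2 and Cacnb4 at -2.07 ± 0.36 and -2.07 ± 0.31. Of 17 prostanoid and leukotriene genes 3 fell and 2 rose (4 and 3 adjusted over the list alone). Ptges fell by 1.99 ± 0.34 and Pla2g5, a phospholipase that releases arachidonic acid, by 2.00 ± 0.47 (n = 2). Of 25 growth factor genes 8 fell and 2 rose (8 and 4 adjusted over the list alone). Ntf3 fell by 1.96 ± 0.27 and 0.89 ± 0.28 on 2 probes (the second at -0.18 in corrected ratios, and no longer called without Indo replicates 1 and 2, at -0.78 and -0.80) and Cntfr, a neurotrophic receptor, by 1.60 ± 0.27. Of 22 apoptosis genes 6 fell, with Apaf1 at -2.39 ± 0.33. Among matrix genes 4 of 19 fell and 3 rose (5 and 3 adjusted over the list alone); Tnc changed by -1.46 ± 0.31, the urokinase receptor Plaur by -1.04 ± 0.23 and urokinase Plau by -0.98 ± 0.25 (no longer called without Indo replicates 1 and 2, at -0.96 and -0.90). Nos1ap changed by -2.73 ± 0.30, the phosphatase Ptpru by -2.80 ± 0.38 and the phosphodiesterase Pde1c by -2.63 ± 0.46 (-1.54 without Indo replicate 3). The retinoic acid receptor Rarb rose by 2.09 ± 0.36, Shank3, a synaptic scaffold, by 1.56 ± 0.33 (n = 2), the acute phase gene Lcn2 by 1.39 ± 0.36 (n = 2) and the peptide transporter Tap2 by 1.26 ± 0.27. None of 25 lists shifted as a whole by camera (lowest adjusted p 0.0984, for ribosomal proteins). By fry 5 lists moved, downward for apoptosis and for glutamate and GABA receptors and upward for glucocorticoid responsive, cholesterol and interferon genes. Cxcl2 rose by 1.42 ± 0.39 (corrected 0.80), a call that ended without each Indo replicate in turn (at 1.51, 1.42 and 1.33), whereas Ptgs2 at 0.70 ± 0.27 and Ccl2 at 0.60 ± 0.35 and 0.14 ± 0.28 did not pass.

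In limma, 507 of 3804 probes passed, 99 higher and 408 lower, against 333 in corrected ratios (108 higher, 225 lower) and 247 in both, with the opposite sign there in 1 of the 490 called probes with a corrected value. As a rough background, the Injured 4 hr arrays tested in the same way against their own PBS pool gave 1074 of 4866 (1021 higher, 53 lower). Those arrays hold far fewer small whole-number ratios than the Indo arrays. Deposited ratios, shifted by -0.03, gave 289 (7.96% higher), quantile normalization 899 (52.8% higher), scale normalization 741 (31% higher) and a block for array set 949 (64.2% higher), against 19.5% in centred ratios. Without Indo replicates 1 and 3 there were 298 and 329.

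The NS398 comparison asks how a cyclooxygenase 2 inhibitor changes the cultured cord, with the pooled DMSO cultures as the only control. The chemokine transcripts Ccl2, Cxcl1 and Cxcl2 rose steeply, and so did a probe of Ptgs2, the transcript of the enzyme that NS398 inhibits. Ccl2, which attracts monocytes, rose by 4.14 ± 0.35 and 3.16 ± 0.28 on 2 probes (n = 3; limma adjusted p = 1.45e-07 and 1.86e-07), Cxcl1 by 4.05 ± 0.38 (adjusted p = 3.89e-07), Ptgs2 by 3.27 ± 0.27 (adjusted p = 1.86e-07) and Cxcl2 by 2.70 ± 0.39. A second Ptgs2 probe had a value on 1 NS398 array, where it stood at 0.12, and was not tested. Some connective tissue genes rose, the proteoglycan Dcn by 2.99 ± 0.35, Mgp by 2.85 ± 0.36, and Col1a2 by 1.73 ± 0.34, and so did Vim, an intermediate filament, by 3.15 ± 0.43. Dhh fell by 3.03 ± 0.31 and the sodium channel Scn8a by 2.60 ± 0.39 (n = 2), although a second Scn8a probe, at -0.46 ± 0.42, did not pass.

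Of 24 cytokines and chemokines 8 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.044; adjusted p = 0.526 with an estimated correlation), and 5 rose in corrected ratios (camera adjusted p = 0.0799). Of 17 NF-kB components and targets 8 rose and 2 fell (camera adjusted p = 0.044; adjusted p = 0.526 with an estimated correlation), among them Nfkbia at 1.79 ± 0.33 and Irf1 at 1.39 ± 0.26. In corrected ratios 6 rose and 2 fell (camera adjusted p = 0.0293; adjusted p = 0.174 with an estimated correlation). Of 16 early response genes 5 rose, with Atf3 at 1.93 ± 0.27 and Dusp1 at 1.83 ± 0.26, and in corrected ratios 7 (camera adjusted p = 0.0295 and 0.00504; adjusted p = 0.526 and 0.0747 with an estimated correlation). Of 9 interferon and antigen presentation genes 4 rose in both kinds of ratio, B2m at 1.77 ± 0.38 among them (5 adjusted over the list alone in centred ratios; camera adjusted p = 0.044 and 0.0293; adjusted p = 0.526 and 0.168 with an estimated correlation). Of 20 vascular and connective tissue genes 5 rose and 2 fell, and 5 rose and none fell in corrected ratios (camera adjusted p = 0.305 and 0.0293, the latter with adjusted p = 0.105 with an estimated correlation).

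Of 19 heat shock genes 8 rose and 1 fell in centred ratios (10 and 2 adjusted over the list alone; camera adjusted p = 0.0295; adjusted p = 0.541 with an estimated correlation), while 2 rose and 4 fell in corrected ones. Hmox1 rose by 2.57 ± 0.41, Hspa1b by 1.99 ± 0.32 and Hspa1a by 1.85 ± 0.33, with its second probe at 0.89 ± 0.34 not past the threshold. The calcium-binding protein S100a6 rose by 2.66 ± 0.43, tissue plasminogen activator Plat by 2.08 ± 0.36 and the prostaglandin D synthase Ptgds by 2.58 ± 0.54 (1.71 without NS398 replicate 3), and the Schwann cell myelin genes Pmp22 and Prx by 3.22 ± 0.52 and 2.00 ± 0.32, from a list with too few measured genes to test. Ptgs1, which encodes cyclooxygenase 1, changed by -2.11 ± 0.59 (n = 2), with a second probe at -0.36 ± 0.33 that did not pass. Plau changed by -2.10 ± 0.25, the calcium channel Cacna1a by -2.27 ± 0.28, Grik1 and the GABA receptor Gabra3 by -1.86 ± 0.30 and -1.83 ± 0.37 (n = 2 for the latter), Apaf1 by -1.96 ± 0.33, and Ntf3 by -2.04 ± 0.27 and -0.80 ± 0.28 on 2 probes, the second no longer called without each NS398 replicate in turn (-0.57, -1.01 and -0.83). Ribosomal proteins rose in 54 of 66 cases in centred ratios (58 adjusted over the list alone; camera adjusted p = 2.78e-15; adjusted p = 0.526 with an estimated correlation) and in 1 of 65 in corrected ones. Oxidative phosphorylation (7 of 20 rose; 9 adjusted over the list alone), proteasome (7 of 26), myelin (3 of 13) and glycolysis (5 of 21) shifted up in centred ratios alone, with estimated-correlation adjusted p between 0.526 and 0.557.

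**Figure D4:**
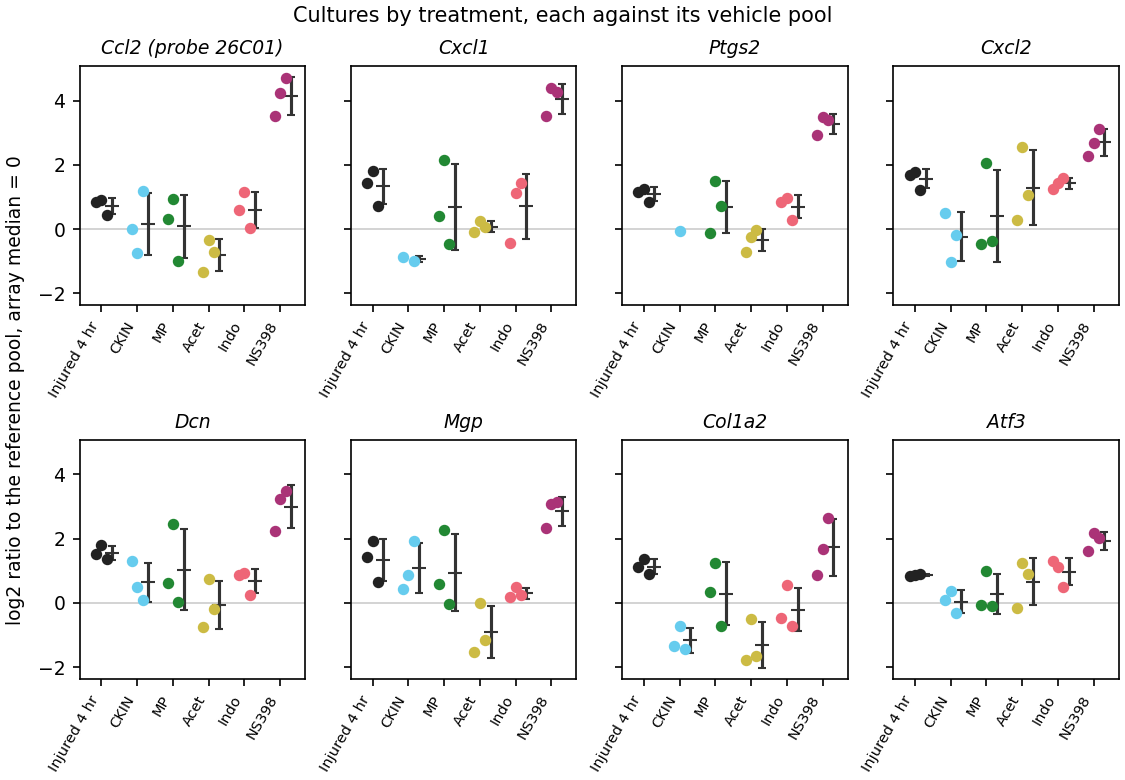
Log2 ratio to the vehicle pool with each array's median at 0 (vertical axis) for 8 genes in the Injured 4 hr group and the 5 treatments. Points are arrays with a value and bars the mean with SD; Ccl2, Cxcl1 and Ptgs2 stand at 4.14, 4.05 and 3.27 in NS398, above every array of the other groups.

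In limma, 986 of 4487 probes passed, 479 higher and 507 lower, against 463 in corrected ratios (177 higher, 286 lower) and 348 in both, with the opposite sign there in 50 of the 961 called probes with a corrected value. The 1074 probes of Injured 4 hr against its own pool are only a rough background here as well. Small whole-number ratios made up between 0.98% and 1.19% of the values on the Injured 4 hr arrays and between 9.33% and 10.9% on the NS398 arrays. Deposited ratios, shifted by -0.98, gave 1977 (2.68% higher) and quantile normalization 1036 (59.2% higher), against 48.6% in centred ratios, and 31 of the 32 named probes kept their call in each of these and in corrected ratios. Without NS398 replicates 2 and 3, 484 and 481 probes passed.

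**Figure D5:**
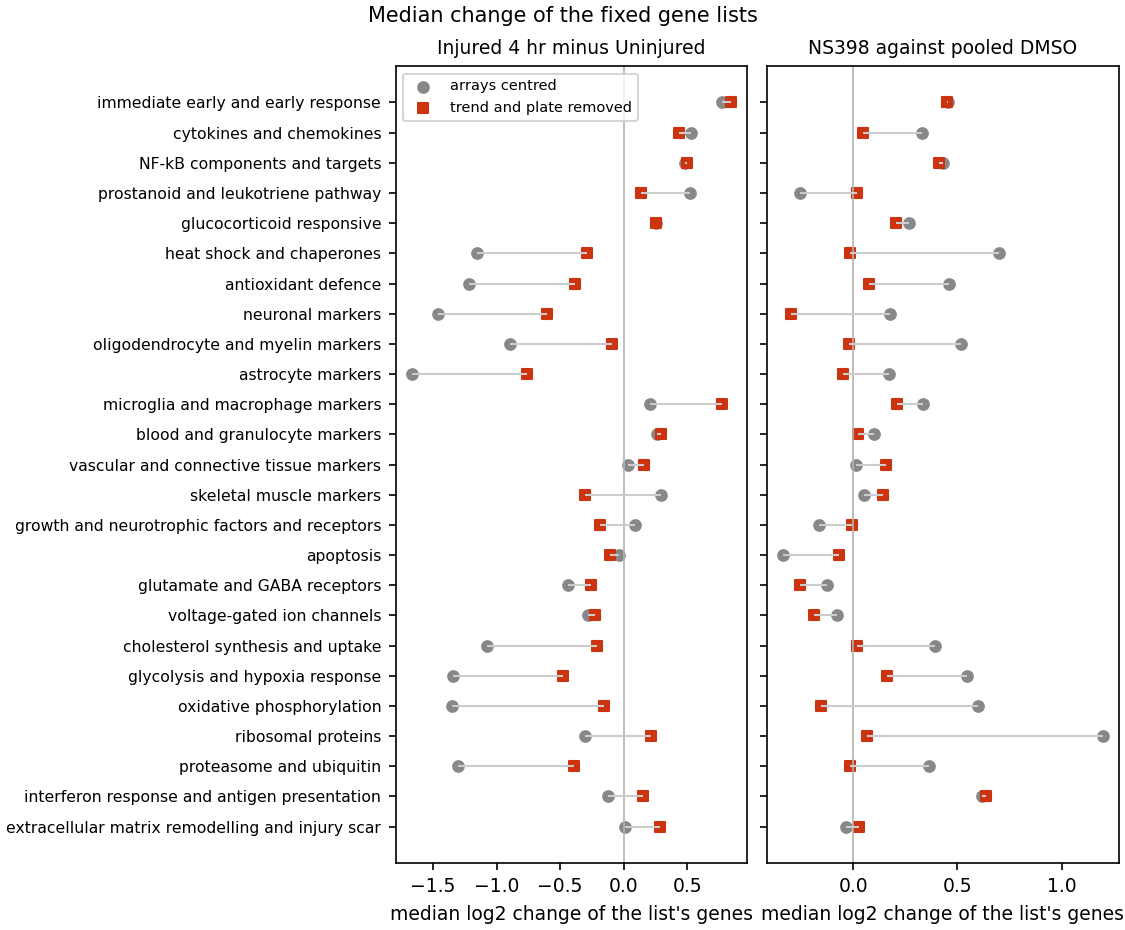
Median log2 change of the measured genes of each tested list (horizontal axis) for Injured 4 hr against Uninjured and for NS398 against pooled DMSO, in centred ratios (circles) and corrected ratios (squares). Neuronal and astrocyte medians in the injury comparison stay below 0 in both, at -0.60 and -0.76 when corrected, while ribosomal proteins in NS398 move from 1.20 to 0.07.

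The difference between NS398 and Indo, each against its vehicle pool, asks whether the 2 cyclooxygenase inhibitors act apart. Ccl2 was higher in NS398 by 3.55 ± 0.49 and 3.03 ± 0.40 on 2 probes (n = 3 per group; limma adjusted p = 0.000341 for both), Cxcl1 by 3.35 ± 0.52 (adjusted p = 0.00132) and Ptgs2 by 2.57 ± 0.39 (adjusted p = 0.00123). Mgp was higher by 2.56 ± 0.51, Dcn by 2.31 ± 0.50, the glycosaminoglycan enzyme Ugdh by 2.24 ± 0.38 and Myc by 2.22 ± 0.49 (n = 3 and 2), and Lcn2 was lower, at -2.29 ± 0.46 (n = 3 and 2). The calls of Ccl2, Cxcl1, Ptgs2 and Ugdh held with each of the 6 arrays left out. Those of Mgp and Dcn ended in 4 of the 6 cases, without NS398 replicates 2 and 3 (Mgp 2.45 and 2.41, Dcn 2.18 and 2.05) and Indo replicates 1 and 3 (Mgp 2.50 and 2.53, Dcn 2.40 and 2.09), that of Myc without NS398 replicates 2 and 3 (2.20 and 2.07) and that of Lcn2 without NS398 replicate 3 (-1.78). In all, 16 of 3682 probes passed, 15 higher and 1 lower, against 29 in corrected ratios (24 higher, 5 lower) and 15 in both. Deposited ratios, shifted by -0.75, gave 15 (20% higher) and quantile normalization 42 (61.9% higher), against 93.8% in centred ratios. Without NS398 replicates 1 and 3 there were 57 and 8, without Indo replicates 1, 2 and 3 there were 8, 26 and 10, and with array set as a block there were 9. Among all lower calls of Indo and NS398 against their pools, 250 probes were shared, where independent lists would share 46.4, and in corrected ratios 111 against 15.7. The overlap is not particular to these 2 treatments: Indo shared 75 of 86 lower calls of MP (9.33 expected) and 42 of 53 of Acet (5.65 expected), and NS398 shared 71 of 87 of MP (9.75 expected). It was weaker for CKIN, with 130 of its 684 lower calls shared by Indo (78.1 expected) and 117 of 690 by NS398 (81.9 expected). In corrected ratios Indo shared 15 of 18 (1.21 expected) and NS398 11 of 18 (1.33 expected) of the CKIN calls. The expectation leaves out whatever the treatment arrays have in common.

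Between the treatments that share the PBS pool, few differences passed. For MP against CKIN limma called 0 of 3634 probes, with 552 at an unadjusted p under 0.05, and 0 in corrected ratios with 405. The count was 8, 2 and 6 without CKIN replicates 1, 2 and 3 and 1 without MP replicate 3. For MP against Acet, Col1a1 was the 1 of 4380 probes that passed, higher in MP by 2.36 ± 0.34 (n = 3 per group; adjusted p = 0.0045), and its second probe at 0.55 ± 0.45 did not pass. The call ended without Acet replicate 3, and 5 and 2 probes passed without MP replicates 2 and 3. For CKIN against Acet 6 of 3751 passed. The lipid enzyme Pcyt1a was higher in CKIN by 2.61 ± 0.40 (n = 2 and 3), Tmeff1 was lower at -2.11 ± 0.39, and both also passed in corrected ratios. The cholesterol enzyme Idi1 at -2.07 ± 0.43, the repressor Zeb1 at -1.54 ± 0.32 and the gut peptide Guca2b at -3.31 ± 0.65 passed in centred ratios, and the remaining probe has no gene listed. None of the 5 was called without CKIN replicate 2 or Acet replicate 3 where it was tested. The count was 28, 0 and 2 without CKIN replicates 1, 2 and 3, and 25, 2 and 0 without Acet replicates 1, 2 and 3.

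Whether a treatment moved injury-changed genes toward fresh cord was measured as the share of injury-called probes whose treatment change had the opposite sign. In 100 simulations of unchanged groups, with the injury test run again on each, this share averaged 65.3%, 66.1% and 66.1% for CKIN, MP and Acet (lowest 60.9%, highest 71.2%), whose Injured 4 hr controls also enter the injury change, and 50.3% and 49.9% for Indo and NS398 (lowest 45.5%, highest 54.8%). The observed shares were 17.9% of 671 probes in CKIN, 32.2% of 687 in MP and 36.2% of 687 in Acet, below the simulated values, and 63.7% of 673 in Indo and 61.7% of 686 in NS398, above them. In corrected ratios the shares were 58.2%, 65.3%, 67.0%, 45.5% and 36.7%, against simulated means of 69.1%, 70.2%, 70.7%, 49.8% and 50%; those of CKIN and NS398 lay below the lowest simulated values of 62.8% and 42.8%, and the other 3 within the simulated range. A share above the simulated values, as movement toward fresh cord would give, was thus seen for Indo and NS398 in centred ratios and for none of the 5 in corrected ones. The simulation draws probes independently and leaves out any spread that many probes of an array have in common. It also gives Indo and NS398 no trend with the stand-in for brightness. Slopes of centred arrays on that stand-in ran from 0.29 to 0.46 in Indo and 0.30 to 0.93 in NS398. They ran from 1.54 to 1.59 in Uninjured and 0.87 to 0.94 in Injured 4 hr. The simulated values therefore cannot say whether the centred shares of Indo and NS398 exceed what such a trend gives. Single arrays ran from 23% to 60.9% in MP and from 26.9% to 64.9% in Acet. With the arrays of treatment and control exchanged in other splits, and the injury sign taken against the PBS pool, the distance from 50% was larger than in the real split for MP (75.8% against 67.8%, taking the larger side) and Acet (79.0% against 63.8%) and smaller for CKIN (73.5% against 82.1%). No movement beyond such splits was therefore seen for MP and Acet. Changes of CKIN, MP and Acet correlated across probes with a mean r of 0.562 (mean covariance 0.264), where shared controls alone gave 0.50 (covariance 0.0967) in simulated centred ratios. In corrected ratios the mean r was 0.475 and the mean covariance 0.162. No simulation was run for corrected ratios, which set the shared Injured 4 hr arrays near 0 by construction. The simulated centred values therefore cannot say what shared controls alone would give there. Indo and NS398 share no array and correlated at 0.50, and at 0.332 in corrected ratios, with no simulation run for this pair. Across probes the values are not independent replicates, so no p-value is given.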

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

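Tests chosen only after the result was seen were the brightness tests on the injury and NS398 patterns, the share of neurons, the correlation within treatments, the reading of NS398 as a response further along, the pooled reference as source of the change common to the treatments, the comparison of NS398 with the other treatments, and every value in corrected ratios or with array set as a block.

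A difference between 2 groups drew attention: 16 probes changed differently in NS398 and in Indo, each against its own vehicle pool, 15 of them higher in NS398. Among the named genes were Ccl2 at 3.55 and 3.03, Cxcl1 at 3.35 and Ptgs2 at 2.57, each higher in 3 of 3 NS398 arrays. The difference was tested directly in limma, and it also holds whatever differs between the DMSO and the ethanol pool. The 10 splits of these 6 arrays are too few for a share under 0.05 (real value 16, highest other 3; 1 of 10 splits gave as many).

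NS398 also stood apart from the other 4 treatments, where 118 of 3167 probes passed in corrected ratios. The chemokine list was shifted up and neuronal markers down (8 of 33 lower in the fit of the list tests, camera adjusted p = 0.000364, but 0.0594 with an estimated correlation). By camera 5 further lists were up, none of them with an estimated correlation. The heat shock, matrix and connective tissue lists did not shift by camera. As far as the stand-in follows brightness, a bias with brightness or source plate is argued against. Of the probes called without the correction, 91.1% were called with it. Array set and a single array are argued against as well. Of the 118 probes, 67 stayed with array set as a term and at least 62 without any 1 NS398 array. In a fit on the 15 treatment arrays NS398 gave 71 probes, and 1 of 100 splits, the real one, gave as many (highest other 3). That is the smallest share these splits can give, for a treatment picked after the data had been seen. The splits also take the arrays as exchangeable, so chance is argued against there but not excluded. A larger share of connective tissue stays open, with the neuronal shift not tested against it. The mean of Col1a2, Dcn and Mgp correlated with that of Ccl2 and Cxcl2 at r = 0.647 over the 12 arrays of the other treatments (permutation p = 0.0244, rho = 0.608 with permutation p = 0.0406, r = 0.501 without the 2 farthest arrays). All of these genes rose in NS398, and they do not stand for the whole lists. The arrays are not exchangeable across treatments, since the 3 Acet arrays hold the 3 lowest means of Col1a2, Dcn and Mgp. Within treatments r was 0.770 (permutation p = 0.0231 over the 1296 orders within treatments). A response to injury further along stays open as well, since 74.0% of 254 injury-called probes had the injury sign in NS398, though 65.4% had it in Indo, against 47.6% in CKIN, 30.7% in MP and 28.7% in Acet, in contrasts that sum to 0; a low level in the DMSO pool cannot be told apart from a rise in the treated cultures, because 0 arrays of unpooled DMSO cultures are among these samples, and the action of the drug itself remains among the open explanations.

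The fall of neuronal and astrocyte genes in the injury comparison may in part be a bias of the ratio with spot brightness. Of the probes lower in centred ratios, 25.2% kept their call once the trend was removed, against 69.2% of the higher probes. The brightness bias thus stays open for most of the fall. For the rise it is argued against only as far as the stand-in follows brightness. The Injured 4 hr arrays make up the stand-in and are also a side of this comparison. In simulated data with a trend, 25 false injury calls remained after correction, against 45 before it. With the same limit, the bias is argued against as the whole cause of the neuronal decline. There the list median moved from -1.46 to -0.60, and the corrected list still passed by camera with an estimated correlation (adjusted p = 0.0207). A lower share of neurons alone would raise the markers of all other cell types alike, but the astrocyte median was -0.76. A lower share of both neurons and astrocytes was not tested and stays open. Loss of transcripts in both cell types after the cut remains open too, as a response to injury, to dissection or to culture, which the design does not separate.

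A change common to all 5 treatments appeared in corrected ratios, which set the Injured 4 hr arrays near 0 by construction: arrays of different treatments correlated at a mean r of 0.30, against 0.379 within a treatment. In deposited ratios the arrays stood little apart, with a mean r of 0.480 between treatments, 0.440 with Injured 4 hr and 0.403 with Uninjured arrays. The pooled PBS reference is argued against as its source, since Indo and NS398 arrays, which carry other pools, correlated with CKIN, MP and Acet arrays at a mean r of 0.282, and array set is argued against as the whole source, since treatment arrays with few missing spots correlated at 0.264 between treatments. Labelling, printing or hybridisation common to the treatment arrays cannot be told apart from a shared response to the drugs: the mean r with the Uninjured arrays was 0.0412, the labels give no processing batch, and exact ratios of small whole numbers made up between 8.08% and 13.2% of the values on the 15 treatment arrays but between 0.320% and 1.19% on the 6 others, a mark of scanning or processing that parts the same arrays. A fall of Ptges or a rise of Barhl1 under each drug may therefore come from either.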

How the results depend on the processing

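Corrected ratios, array set as a block and the comparison with the other 4 treatments were chosen after the data had been seen; the rest were planned. Of the 159 called probe results named in the report, all kept their call with robust moderation and 157 with array weights; 85 kept it in deposited ratios, where 63 were no longer called and 11 reversed, 129 under quantile and 141 under scale normalization, 128 in corrected ratios and 120 with array set as a block. The cause was not tested except where the setting itself shows it. The number of arrays and the missing spots of 10 of them limit what can be called.

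Counts under each setting follow, beside the counts of the report. In deposited ratios: injury 2428, CKIN 2232, MP 3171, Acet 3372, Indo 289, NS398 1977, MP against Acet 0, CKIN against Acet 2, Injured 4 hr against its pool 4408, by the uncentred medians. Under quantile normalization: injury 20, MP 35, Indo 899, NS398 against Indo 42, MP against CKIN 8, CKIN against Acet 104. Under scale normalization: injury 33, CKIN 1229, MP 648, Acet 507, MP against CKIN 2, CKIN against Acet 20. In corrected ratios: injury 295, CKIN 28, MP 17, Acet 31, Indo 333, NS398 463, NS398 against Indo 29, MP against Acet 2, CKIN against Acet 10, and Injured 4 hr against its pool 0 by construction. With array weights: injury 1909, MP 933, Acet 573, NS398 against Indo 26, MP against CKIN 3, MP against Acet 28, CKIN against Acet 46, Injured 4 hr 2044. With only the compared arrays in the fit: injury 1825, MP 24, Acet 131, Indo 289, NS398 125, NS398 against Indo 6, MP against Acet 0, CKIN against Acet 0, Injured 4 hr 2050. Against the PBS pool: MP 1374, Acet 1443. With array set as a block: CKIN 8, MP 33, Indo 949, NS398 against Indo 9, MP against CKIN 3, MP against Acet 8. On probes measured on all 21 arrays: Indo 241, NS398 580 and MP against Acet 0, where fewer probes were tested, but MP against CKIN 1 and CKIN against Acet 40, more than the 0 and 6 of the report. Without a filter on missing values: NS398 against Indo 45, MP against CKIN 19, MP against Acet 3, CKIN against Acet 49. Without the probes of smallest spread, where fewer were tested: Indo 239, NS398 636, CKIN against Acet 2. Against the other 4 treatments: CKIN 27, MP 1, Acet 14, Indo 0, NS398 118.

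Gene lists called by camera numbered 13 for injury, 5 for CKIN, 1 for MP, 1 for Acet, 0 for Indo and 10 for NS398. With an estimated correlation there were 1, 0, 0, 0, 0 and 0. By fry there were 14 for CKIN, 0 for MP, 2 for Acet and 5 for Indo. In corrected ratios there were 0 for CKIN, 2 for MP, 0 for Acet and 4 for NS398, in deposited ratios 2 for MP, 0 for Acet and 1 for Indo, under quantile normalization 2 for MP and 1 for Indo, and for CKIN against the other treatments 0. The share of injury-called probes moved the other way was 17.9% for CKIN and became 36.7% over all measured probes. In corrected ratios it was 58.2% for CKIN, 65.3% for MP, 67.0% for Acet, 45.5% for Indo and 36.7% for NS398. The correlation of Indo with NS398 was 0.736 on probes measured on all arrays and 0.332 in corrected ratios, and that of CKIN, MP and Acet with Indo and NS398 moved from 0.114 to 0.556 against the reference pools and 0.35 in corrected ratios.

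Without 1 replicate, counts ran from 354 to 493 for injury, 205 to 549 for CKIN, 3 to 598 for MP, 0 to 122 for Acet, 298 to 379 for Indo, 481 to 962 for NS398, 8 to 57 for NS398 against Indo, 0 to 8 for MP against CKIN, 0 to 5 for MP against Acet and 0 to 28 for CKIN against Acet, and the share of injury-called probes moved the other way from 16.1% to 21.3% for CKIN, 26.8% to 43.5% for MP, 26.7% to 48.3% for Acet, 60.7% to 65.2% for Indo and 55.8% to 65.3% for NS398. Fewer arrays lower the counts by construction; why some omissions raised them was not tested. Of the single-probe outcomes with 1 replicate left out, 554 were as reported and 179 no longer called.

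Directions that reversed were, in deposited ratios, CKIN Nfkbia 0.19, MP Il1a 0.69, Apaf1 0.19, Grm6 0.041, Grik1 0.22, Cacna1e 0.26, Cacnb2 0.085 and 1 Nos3 probe 0.20, and Acet Bid 0.24, Grm6 0.070 and 1 Col1a1 probe 0.37, all by the shift of the median. Under scale normalization injury Gfap stood at 0.16. Against the PBS pool, CKIN S100b on 1 probe stood at 0.17 and Rps24 at 0.24, and that S100b probe at 0.11 in corrected ratios.

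A block for replicate number gave 711 probes for injury, 785 for CKIN, 121 for MP, 86 for Acet, 519 for Indo, 1010 for NS398 and 23 for NS398 against Indo, and 0, 1 and 6 for the comparisons between CKIN, MP and Acet. Replicate numbers were not taken as pairs: the mean correlation of samples with the same number ran from -0.04 to 0.27 over the comparisons, and in none did every pair exceed 0.1. The highest mean was that of MP against Acet, with 0.338, 0.451 and 0.009 for numbers 1, 2 and 3. Samples with different numbers averaged -0.133 there. A pairing by number is thus not excluded for these 2 groups.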

Other observations

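All comparisons of a treatment with the other treatments below were chosen after the data had been seen, in corrected ratios; the Injured 4 hr arrays are no term of the contrasts but enter through the correction and, except in fits on the treatment arrays alone, the spread, and the 5 contrasts are not independent, since they sum to 0.

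Against the mean of the other 4 treatments, NS398 differed most, with 118 of 3167 probes past the threshold (65 higher, 53 lower), of which 72 also passed with the same sign in centred ratios. Ccl2 was higher by 4.01 ± 0.34 and 3.42 ± 0.24 (SE, n = 3 and 12) on 2 probes, Cxcl1 by 3.75 ± 0.36, Cxcl2 by 1.71, Nfkbia by 1.63 and Atf3 by 1.54. The list counts that follow come from the fit of the list tests, in which missing values were filled. They are not counts among the 118 probes, and some exceed the members found there. Of 20 vascular and connective tissue genes 4 were higher (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0944), Col1a2 by 2.23 and Dcn by 2.19 among them. Of 19 matrix remodelling genes 4 were higher and 4 lower (camera adjusted p = 0.592), with Timp1, which inhibits matrix proteases, at 2.21 and the matrix enzymes Plau and Lox at -1.20 and -1.02. Of 19 heat shock genes 2 were higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.941). Among lower genes were the adhesion gene Chl1 at -2.68, the myelin gene Mag at -2.07, the neurofilament Nefm at -1.80 and the synaptic vesicle gene Syp at -1.34, while the myelin list, with 1 of 13 lower, did not shift as a whole (camera adjusted p = 0.485). Cytokines and chemokines shifted up with 5 of 24 past the threshold (camera adjusted p = 0.0019; adjusted p = 0.0471 with an estimated correlation), and neuronal markers shifted down with 8 of 33 (11 adjusted over the list alone; camera adjusted p = 0.000364; adjusted p = 0.0594 with an estimated correlation). By camera 5 further lists shifted up, and none of them with an estimated correlation: NF-kB components and targets (6 of 17 higher; 6 and 1 lower adjusted over the list alone; camera adjusted p = 0.0019, estimated 0.0796), early response (2 of 16; 3 over the list alone; 0.00587 and 0.0594), ribosomal proteins (1 of 65; 0.00587 and 0.108), prostanoid (3 of 17 higher, 1 lower; 6 and 1 over the list alone; 0.0396 and 0.0804) and interferon genes (2 of 9; 4 and 1 lower over the list alone; 0.0396 and 0.108).

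CKIN gave 27 probes (13 higher, 14 lower), 12 of them in both kinds of ratio, with Cxcl1 at -1.90 ± 0.42 (limma adjusted p = 0.0386), the DNA repair gene Rad50 at -2.18 and the transcription factor Ptf1a at 1.03. For MP the 1 probe that passed, in both kinds of ratio, was Il1a at -1.35 ± 0.23 (limma adjusted p = 0.0307), with 308 probes at an unadjusted p under 0.05. In the fit of the list tests, neuronal markers were shifted up in MP with 2 of 33 past the threshold (9 adjusted over the list alone, camera adjusted p = 0.027 with an estimated correlation). None of them passed in the probe fit, where Il1a alone did. Astrocyte markers had a median of -0.351 in MP, with 0 of 13 past the threshold. That list was lower by fry (adjusted p = 0.0191) but not by camera (adjusted p = 0.114). Acet gave 14 probes (1 higher, 13 lower), 4 of them in both, with Mgp at -2.58, Igfbp2 at -2.42 and Ccl2 at -2.30 on 1 probe and, in corrected ratios alone, -1.43 on the other. The haemoglobin gene Hbb stood at 1.22 in CKIN and -1.32 in Acet, in corrected ratios alone. Blood and granulocyte markers were shifted down in Acet with 4 of 9 lower in the fit of the list tests (1 higher and 4 lower adjusted over the list alone). Their adjusted p was 0.0105 by camera and 0.000679 by fry, but 0.121 with an estimated correlation. Indo gave 0 probes in limma in both kinds of ratio, with 262 at an unadjusted p under 0.05. In fits on the 15 treatment arrays alone, CKIN, Acet and Indo gave 0 probes in limma (332, 221 and 204 at an unadjusted p under 0.05). Any split reaches 0, as all 100 of 100 did (highest other 3), so the splits say nothing on chance for these 3. MP gave 1, which 16 of 100 splits reached (highest other 3), so chance cannot be excluded for MP in that fit.

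For the comparisons of 3 arrays with 3 arrays, 10 splits are too few for a share under 0.05. The real value and the highest of the other splits were 690 and 1 for injury, 749 and 0 for CKIN, 90 and 1 for MP, 62 and 0 for Acet, each with 1 split as large, 6 and 1 for CKIN against Acet, with 1 split as large, and 0 and 2 for MP against CKIN, with all 10 as large, as any split reaches 0. For MP against Acet they were 1 and 482, with 3 splits as large. The split with 482 probes follows the array sets, which points to a structure of the arrays, and with array set as a block MP against Acet gave 8 probes.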
